A study of Homo sapiens with 8 samples.

How the data were processed

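RNA sequencing was done on HCT116 and HT29 cells 48 h after transfection of siRNA at 15 nM with a lipid reagent, per the labels, with 1 library for each of 4 siRNAs (NC, RPL9, RPL17, RPL27) in each line. The series title and design name only NC and RPL9 siRNA, while the sample labels give all 4, which the levels of the targeted genes were checked against. Per the submitters' processing notes, base calls were made with CASAVA 1.8.2 and reads were aligned with TopHat2 2.0.9 to hg19. The deposited values are RPKM, 1 value per gene symbol and library for 19124 genes, without repeated symbols. The rule by which reads were assigned to genes is not given in the sources used here. Values times transcript length in kb summed to 21.2 to 21.6 M (mega) per library (16.9 in HT29 NC), and to 1.67 to 1.74 M after division by the number of exons, as a sum of exon RPKMs would. Reads per library were estimated from 1182 single-exon genes. The most frequent value times kb within a fixed low window was taken as 1 read. The window bounds the estimate. At that value 48.1% to 58.5% of low values lay within 0.05 of a whole number of reads, including the values that set it. Read counts were not analysed here, so no counting interval was computed.

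Genes that carry sex-linked identity (44 genes) were left out. Values were taken as log2(RPKM + 1), and 14272 genes with a mean of at least 1 RPKM over the 8 libraries were tested. limma 3.58.1 (trend) in R 4.3.3 was fitted with terms for cell line and siRNA, which leaves 3 residual degrees of freedom, and the contrasts were each RPL siRNA against NC, their mean against NC, each RPL siRNA against the mean of the other two, and HCT116 against HT29. The difference of the RPL siRNA effect between lines came from a fit with line, any RPL siRNA and their interaction, which treats the 3 RPL siRNAs of a line as replicates. All tests are two-sided, and p values were adjusted over the tested genes by the Benjamini-Hochberg method with a threshold of 0.05. The replicates are the 2 cell lines for the siRNA contrasts and different siRNAs in the other fits, and no siRNA was repeated within a line. Named genes were 12 fixed in advance and, among genes past the threshold, those with the highest and lowest log2 fold changes: 12 each way for the mean contrast (same direction in all 6 RPL siRNA libraries), 8 for each siRNA against NC (same direction in both lines), 5 for each siRNA-specific contrast, 6 for the interaction and 10 for the lines. Where fewer passed, places were filled, as values and not calls, by the genes with the largest change in the line where it was smaller. Not all filled genes are given in the text, and some genes and 1 gene list are counted but not reported here.

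Gene lists were fixed before the data were examined, as were the comparisons, the naming rule, the thresholds and the first set of other settings. They were large and small subunit ribosomal proteins, ribosomal protein paralogs, translation factors with 5' TOP messages, ribosome biogenesis factors, G1/S and DNA replication, G2/M and mitosis, NF-kB targets, ID genes and BMP targets, the ATF4 and amino acid response, the unfolded protein response, interferon-stimulated genes, immediate early genes, the BCL2 family and caspases, cholesterol biosynthesis, hypoxia and glycolysis, Wnt targets, intestinal differentiation, adhesion genes, replication-dependent histones, and markers of fibroblasts, leukocytes and endothelium. Lists of small nucleolar RNA hosts and of mitochondrially encoded genes had too few measured members for a value. Lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated per list; robust variances used statmod 1.5.0. Within a line, list medians were set against 10000 random lists drawn from genes of like mean level.

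The alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5, quantile normalization, median-centring, limma without trend and with robust variances, no cell line term, each library left out in turn, a fit of any RPL siRNA against NC, and a smaller size rule for single libraries. Chosen after seeing the data were the removal of each library's trend with transcript length (a spline with 5 degrees of freedom, over 13729 genes with a length matched from the GRCh38 annotation), the same with GC content, fits without both NC libraries, and fits of 1 line alone. On simulated data with the spread of the 8 libraries, the mean contrast recovered 18.0% of changes of 1 (log2) and 85.0% of changes of 2, with 3 false calls among 13872 genes. The RPL9 contrast recovered 3% and 68.0% with 7 false calls, and the interaction 0% and 0% with 0. At 0.4 of that spread the mean contrast recovered 97% and 100%, the RPL9 contrast 91% and 100% and the interaction 58% and 97%, with 4, 4 and 10 false calls. Of 25 unshifted lists camera called 0, and a list of 40 genes shifted by 0.5 had an adjusted p of 5.4e-18. The simulated genes varied independently, so this does not test camera on lists whose members are correlated. Each simulated library was given the same spread, taken from the fit with line and siRNA terms. In the data the HT29 NC library deviated more than the others. The recovery rates and false calls therefore need not hold for the real tests. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.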

Results

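Messenger RNA was profiled in HCT116 and HT29, established cell lines from human colorectal cancers, after transfection with a negative control siRNA (NC) or with an siRNA against a protein of the large ribosomal subunit, RPL9, RPL17 or RPL27. Each of the 2 lines was given each of the 4 siRNAs at 15 nM, and RNA was taken 48 h later, which made 8 libraries with 1 library per line and siRNA. No line has a replicate of any siRNA, so values within a line carry no replicate error, and the tests of the siRNAs take the 2 lines as the replicates, while the tests of the line difference, of the lines and within 1 line take different siRNAs as replicates. The deposited values are RPKM for 19124 genes per library. The most frequent low value of single-exon genes, taken as 1 read, put the libraries at 20.7 to 26.5 M (mega) reads. That value was sought in a fixed window, so these depths are rough estimates. Between 13.0% and 15.5% of the genes were listed at 0. The values behave like RPKMs added over the exons of a gene, so levels are compared between libraries and not between genes. The HT29 NC library differed from all others in its dependence on transcript length: over 9289 genes its deviation from the other 7 libraries had a rank correlation of -0.64 with length, against -0.11 to 0.09 for the other libraries. Its median deviation went from 0.70 (log2) in the bin of shortest transcripts to -1.40 in the bin of longest, so every value against NC in HT29 carries this trend.

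**Figure D1:**
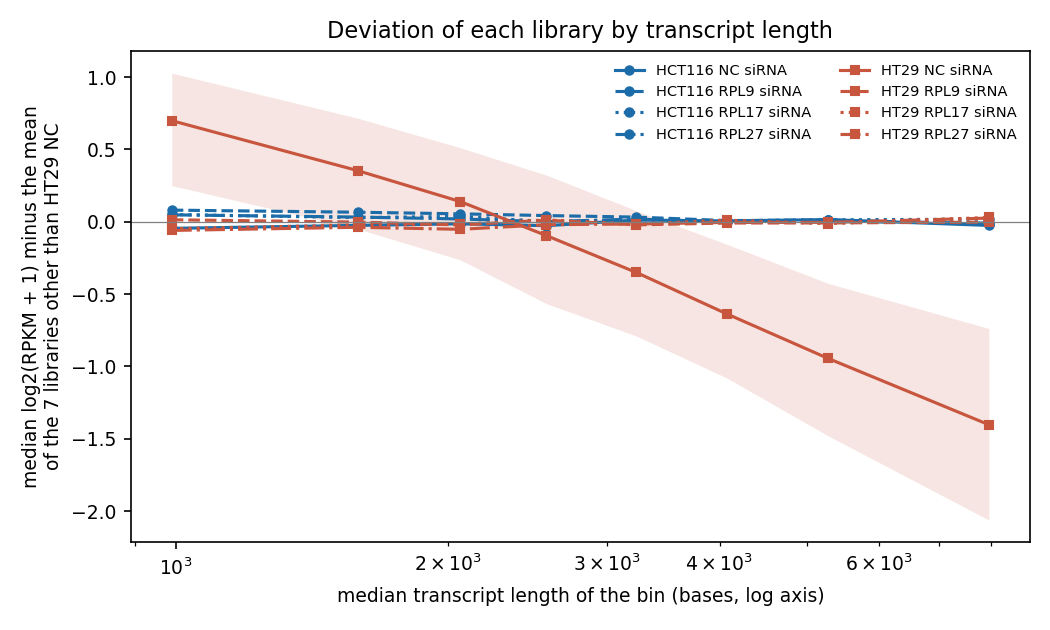
Median difference (log2) of each library from the mean of the 7 libraries other than HT29 NC, in bins of transcript length (bases, log axis), with the middle 50% of genes shaded for HT29 NC. The HT29 NC line runs from 0.70 in the shortest bin to -1.40 in the longest, while the lines of the other libraries stay near 0.

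The targeted genes were read first, as a check of the labels. RPL9 stood at 5560 RPKM in the RPL9 siRNA library of HCT116 against 17432 in NC, and at 5245 against 35729 in HT29, that is at 31.9% and 14.7% of NC. RPL17 stood at 38.5% of NC under RPL17 siRNA in HCT116 and at 18.7% in HT29, and RPL27 at 26.7% and 13.7% under RPL27 siRNA. Against the mean of the other two RPL siRNA libraries of the same line, which does not use the NC library, the targeted genes stood at 29.7% and 29.8% (RPL9), 34.1% and 29.1% (RPL17) and 29.2% and 28.97% (RPL27) in HCT116 and HT29. Every library labelled with an RPL siRNA thus had its own target lowest among the 4 libraries of its line. RPL27 mRNA was also low under RPL17 siRNA, at 4723 RPKM in HCT116 and 4754 RPKM in HT29, or 61.7% and 29.3% of NC. The levels of ribosomal protein genes rest on reads that processed pseudogenes can share, and RPL17 overlaps a read-through gene, so these levels are uncertain in absolute terms.

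**Figure D2:**
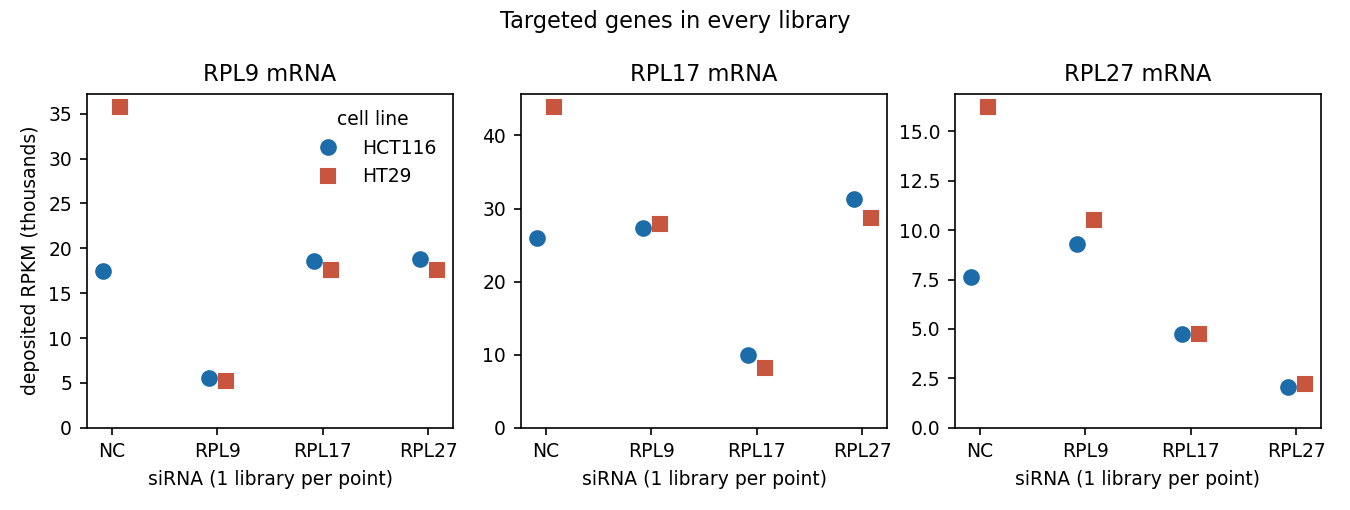
RPKM, on an axis in kilo-RPKM, of the 3 targeted genes in each of the 8 libraries, by siRNA, with HCT116 as circles and HT29 as squares and 1 library per point. In each panel the library given the matching siRNA is lowest in both lines, at 2045 to 10004 RPKM.

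The mean of the 3 RPL siRNAs against NC asks which genes respond to a loss of any of these proteins in both lines. Among the genes that were higher were CDKN1A by 2.16 (log2; SE 0.15; adjusted p = 0.022), BTG2 by 2.17 (SE 0.21; adjusted p = 0.048), FAS by 2.11 (SE 0.21; adjusted p = 0.048), PLK2 by 1.67 (SE 0.13; adjusted p = 0.022) and SUSD6, listed as KIAA0247, by 2.35 (SE 0.23; adjusted p = 0.048). CDKN1A went from 225 RPKM in NC to 958 to 1195 RPKM in HCT116 and from 198 to 762 to 864 RPKM in HT29. Genes of serine and asparagine synthesis were lower: ASNS by -2.52 (SE 0.19), PHGDH by -2.51 (SE 0.20) and PSAT1 by -1.80 (SE 0.14), with PCK2 at -2.53 (SE 0.18), all with an adjusted p of 0.022, and the stress gene NUPR1, listed at a mean of only 3.46 RPKM, at -3.42 (SE 0.35; adjusted p = 0.048). The proliferation genes HMGB2 (-1.71), PBK (-1.65), STMN1 (-1.56) and NUF2 (-1.46) were lower as well. The other named genes past the threshold were higher, MGAM (4.30), SCEL (3.94), COL4A1 (3.22), CPA4 (2.69), MSH4 (2.55) and ZFP36L1 (1.65). SCEL is a gene of HT29 (154 RPKM in NC, 1667 to 4926 RPKM under the RPL siRNAs), and its 8.53 to 14.4 RPKM in HCT116 came to 0.29% to 0.51% of the HT29 level, while 85 genes of HT29 were read in the same HCT116 libraries at a median of 0.19% to 0.54% of theirs. MGAM and COL4A1 had means of only 16.7 and 15.8 RPKM.

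In this comparison limma called 24 of 14272 genes at an adjusted p under 0.05, 15 higher and 9 lower, and all moved the same way in the 6 RPL siRNA libraries. Of the called genes, TPM4 (1.42), SEMA7A (1.62) and TIGAR (listed as C12orf5, 1.46) fall outside the naming rule and were picked after their values were seen. An unadjusted p under 0.05 was reached by 3508 genes. The count depends on each library. With 1 NC library left out, the effect sizes of the mean contrast are those of the line that keeps its NC library. The direction of the 24 genes was thus fixed in the fit without the HT29 NC library. Without the HT29 NC library 989 genes were called higher and 852 lower, among them all 24 in the same direction. After the trend of each library with transcript length was removed, 366 were called higher and 507 lower, again with all 24 in the same direction, and 723 genes were shared by these lists, all in the same direction. Without the HCT116 NC library 6948 genes were called, and without any 1 of the 6 RPL siRNA libraries limma called 0, with adjusted p values of 0.15 to 0.30 for the genes that the naming rule picked. With the HCT116 libraries alone 0 genes were called (2532 at an unadjusted p under 0.05), and with the HT29 libraries alone 4852, or 0 and 2655 after length correction. These single-line fits hold 1 NC library against 3 siRNAs, so their p values carry no spread between NC libraries. Quantile normalization gave 36 higher and 47 lower, and median-centring gave 5 and 2.

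Among genes fixed in advance, MDM2 went from 986 RPKM in NC to 3696 to 5026 RPKM in HCT116 and from 168 to 2622 to 3646 RPKM in HT29 (mean log2 difference 3.10, SE 0.44, adjusted p = 0.066). MDM2 passed the threshold after length correction, at 2.27 with an adjusted p of 0.0029. ID1 stood at -1.19 (SE 0.26; adjusted p = 0.093), MYC at 0.60 (SE 0.22; adjusted p = 0.18), RELA at 0.71 (SE 0.19; adjusted p = 0.12) and NFKBIA at 0.11 (SE 0.21; adjusted p = 0.77). The proteins of RPL5 and RPL11 bind MDM2 outside the ribosome. RPL5 stood at -0.03 in HCT116 and -0.85 in HT29, and RPL11 at 0.39 and -0.71; in the test of this line difference RPL5 had an adjusted p of 0.0501 and RPL11 of 0.0012, and after length correction 0.65 and 0.064. Without the HT29 NC library the mean contrast rests on the HCT116 NC library alone, and RPL11 stood at its HCT116 value of 0.39.

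Gene lists were compared in the same contrast. The 30 genes of G2/M and mitosis had a median of -0.98, with 1 called over all genes and 24 adjusted over the list alone (camera adjusted p = 7.2e-19; adjusted p = 0.20 with an estimated correlation). For the 32 genes of G1/S and DNA replication the median was -0.60, with 0 called by limma over all genes and 20 lower adjusted over the list alone (camera adjusted p = 9.4e-13; adjusted p = 0.073 with an estimated correlation). The 31 genes of the ATF4 and amino acid response had a median of -0.76, with 4 called lower over all genes and 19 lower and 2 higher adjusted over the list alone (camera adjusted p = 1.3e-11; adjusted p = 0.073 with an estimated correlation). These 3 lists kept their direction and their camera call in all 17 alternatives, with medians of -1.18 to -0.72 (G2/M), -0.80 to -0.47 (G1/S) and -0.96 to -0.66 (ATF4).

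**Figure D3:**
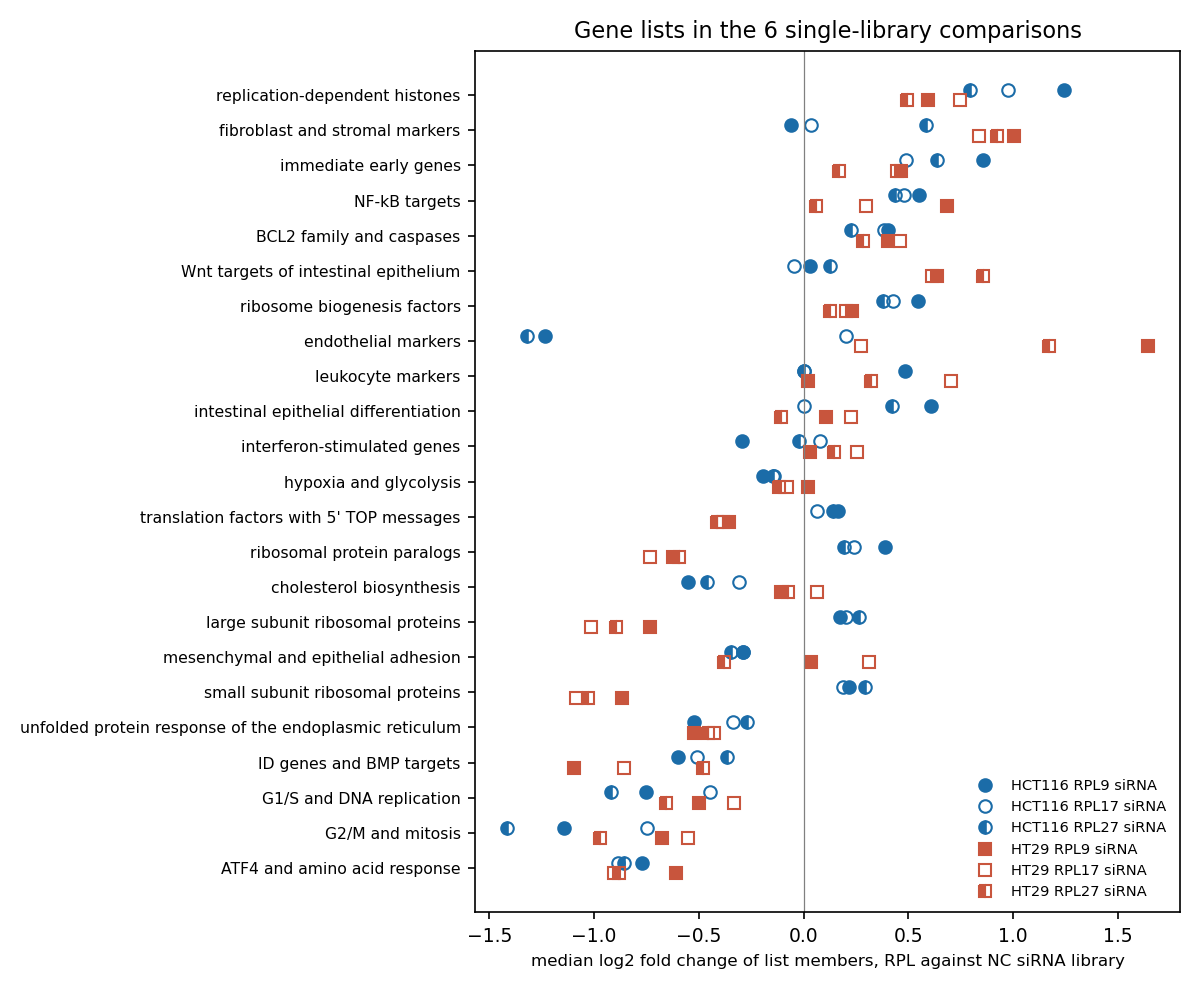
Median log2 fold change of each gene list in the 6 comparisons of an RPL siRNA library with the NC library of the same line, HCT116 as circles and HT29 as squares. The ribosomal protein lists lie above 0 in HCT116 and below 0 in HT29.

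Other lists also passed by camera in the mean contrast. The 36 ribosome biogenesis factors had a median of 0.30 and 14 genes higher adjusted over the list alone (camera adjusted p = 0.0022; adjusted p = 0.33 with an estimated correlation). The 18 genes of the unfolded protein response stood at -0.48 (camera adjusted p = 0.0022; adjusted p = 0.20 with an estimated correlation), with 8 lower and 1 higher adjusted over the list alone. Immediate early genes stood at 0.44 (camera adjusted p = 0.0058), ID genes and BMP targets at -0.38 (0.0075), cholesterol biosynthesis at -0.21 (0.0063) and replication-dependent histones at 0.79 (0.019). For these 4 lists the adjusted p was 0.33 to 0.34 with an estimated correlation. For all 6 lists limma called 0 genes over all genes. Adjusted over the list alone, 6 immediate early genes and 3 histone genes were higher, and 3 ID or BMP genes and 4 cholesterol genes were lower. Without the HCT116 NC library the camera adjusted p rose to 0.72 for ribosome biogenesis, 0.099 for the unfolded protein response, 0.59 for immediate early genes, 0.44 for cholesterol biosynthesis and 0.72 for histones, and without the HT29 NC library it was 0.18 for ID genes and BMP targets. With a mean of at least 5 it was 0.055 for histones. In HT29 the median of all genes lay 0.17 to 0.20 above NC, about where the ribosome biogenesis factors stood in that line (0.17).

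Ribosomal protein genes themselves went opposite ways in the lines. The 47 genes of the large subunit had a median of -0.34 and the 32 of the small subunit -0.38 in the mean contrast, with 0 genes called by limma over all genes and 0 adjusted over either list alone. Their camera adjusted p values were 5.8e-08 and 1.7e-05, and adjusted p = 0.61 with an estimated correlation for both. In HCT116 the medians were 0.20 and 0.23, and in HT29 they were -0.91 and -0.995. Without the HT29 NC library the contrast reduces to the HCT116 difference, so both lists again stood at 0.20 and 0.23. Under quantile normalization they stood at -0.095 and -0.13 and passed no longer (0.085 and 0.14), nor did the small subunit after length correction (-0.16; 0.064). Ribosomal protein mRNAs are short, at the end of the length range where the HT29 NC library read high.

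The remaining lists reported here passed no camera threshold in the mean contrast. NF-kB targets had a median of 0.29 (camera adjusted p = 0.055), which passed at 0.59 without the HT29 NC library (0.0018) and at 0.36 without the HT29 RPL27 siRNA library (0.040), and also with a pseudocount of 5 (0.049), a mean of at least 5 (0.0068), length correction (0.013) and length and GC correction (0.0047). In these 6 settings the adjusted p was 0.18 to 0.53 with an estimated correlation. The other medians were 0.61 for Wnt targets, 0.40 for the BCL2 family and caspases, 0.33 for intestinal differentiation genes, 0.06 for interferon-stimulated genes, -0.02 for adhesion genes, -0.14 for translation factors with 5' TOP messages, -0.15 for hypoxia and glycolysis and -0.15 for ribosomal protein paralogs. The lists of cell types not in these cultures held few measured genes: 6 fibroblast and stromal markers stood at 0.40, 7 leukocyte markers at 0.36 and 3 endothelial markers at -0.25. Without the HT29 NC library the BCL2 family list and the hypoxia list passed (0.028 and 0.029), and the translation factors passed without the HCT116 NC, HCT116 RPL17 siRNA or HCT116 RPL27 siRNA library (2.4e-05, 0.043 and 0.040), and at 0.14 in the opposite direction without the HT29 NC library (0.017). The BCL2 family list also passed after length (0.042) and length and GC correction (0.028), and Wnt targets with a mean of at least 5 (0.0496). With an estimated correlation the adjusted p of these lists was 0.39 to 0.67 in each such setting.

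**Figure D4:**
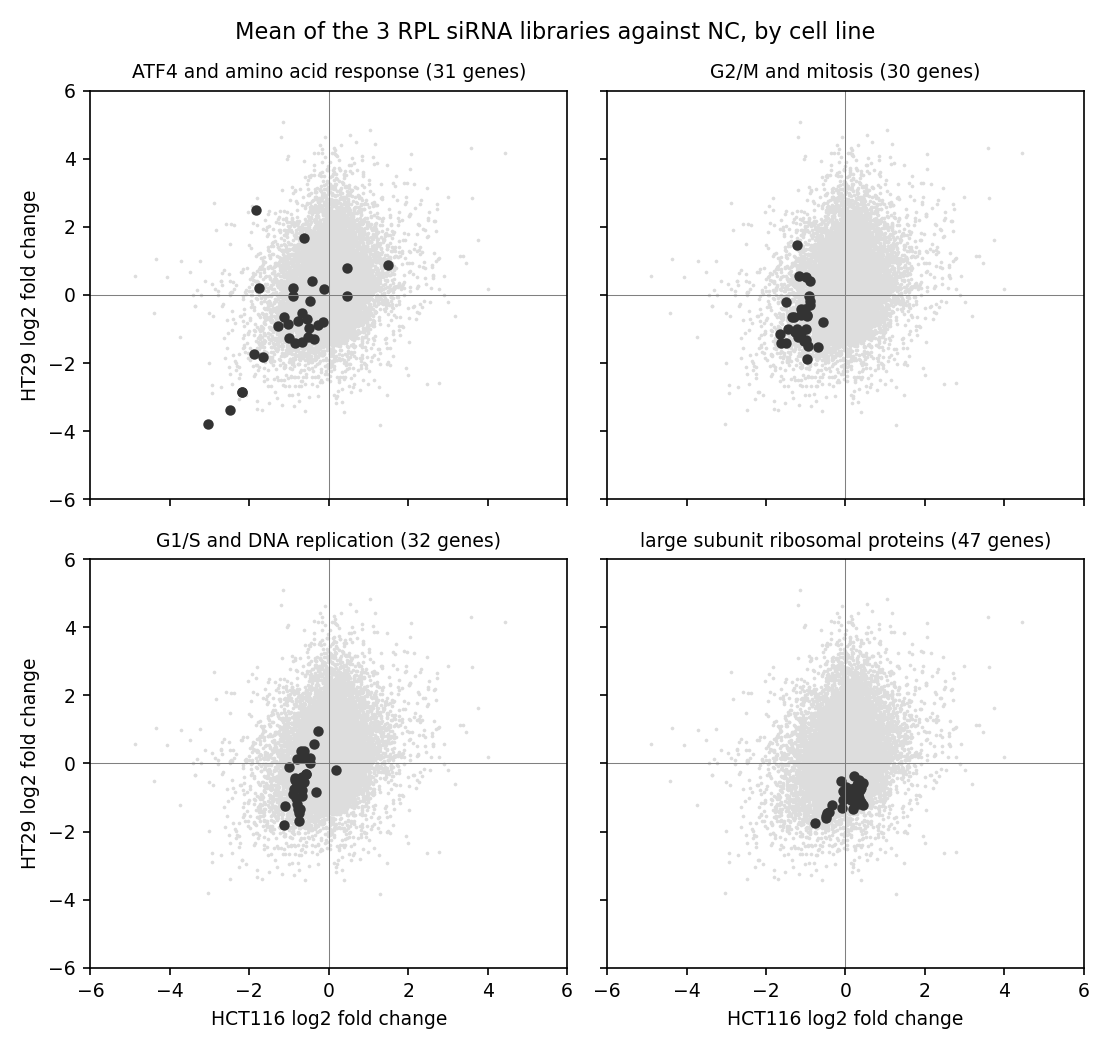
Mean log2 fold change of the 3 RPL siRNA libraries against NC in HCT116 (horizontal) and HT29 (vertical), with all tested genes in grey and the members of 4 gene lists in black. Most ATF4, G2/M and G1/S genes lie below 0 in both lines, while the large subunit ribosomal protein genes lie near 0.20 in HCT116 and -0.91 in HT29.

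Each siRNA was also set against NC on its own. Under RPL9 siRNA the carboxypeptidase gene CPA4 was higher by 3.55 (SE 0.17; adjusted p = 0.011), with 3.51 in HCT116 and 3.59 in HT29. Under RPL17 siRNA CPA4 was higher by 2.76 (SE 0.17; adjusted p = 0.026). Limma called 1 gene for RPL9, 2 for RPL17 and 0 for RPL27 siRNA, where 2912, 2243 and 2387 genes had an unadjusted p under 0.05. The targets themselves stood at -2.21 (RPL9; SE 0.31; adjusted p = 0.098), -1.90 (RPL17; SE 0.26; adjusted p = 0.19) and -2.39 (RPL27; SE 0.28; adjusted p = 0.10). After length correction RPL9 and RPL17 passed, at -1.95 (adjusted p = 0.0073) and -1.61 (0.013). RPL27 had no matched transcript length. Without the HT29 NC library 2177, 982 and 1435 genes were called, without the HCT116 NC library 6597, 6314 and 6374, after length correction 538, 52 and 272, and without any 1 of the 6 RPL siRNA libraries 0.

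Genes with a large difference in both lines that passed no threshold were named by the size rule, as values. Under RPL9 siRNA they were SCEL (4.47), COL4A1 (3.92), MGAM (3.52), SCN2A (3.49) and CPEB2 (3.19) upward and ORM1 (-3.79) and NUPR1 (-3.74) downward. Under RPL17 siRNA they were MGAM (5.17), SCEL (4.03), FLG (3.45) and BIRC3 (2.66) upward and NUPR1 (-3.58), ZNF705G (-3.40), CCDC153 (-3.02) and SSX1 (-2.93) downward. Under RPL27 siRNA they were MGAM (4.21), SCEL (3.34), ZNF19 (3.02) and MXD1 (3.02) upward and P4HA3 (-3.54), CIART, listed as C1orf51 (-3.53), and TMSB15A (-2.75) downward. Many of these are low genes with wide errors, such as ORM1 (mean 4.22 RPKM; SE 0.80 under RPL9 siRNA) and ZNF705G (mean 7.31 RPKM; SE 1.02 under RPL17 siRNA). The log2(RPKM + 1) scale shrinks a change in such genes, while a choice by size favours values that noise made large. G2/M genes had medians of -1.02, -0.65 and -1.22 under RPL9, RPL17 and RPL27 siRNA, and ATF4 response genes of -0.67, -0.83 and -0.70.

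The comparison of each RPL siRNA with the mean of the other two asks what is specific to 1 target, and does not use the NC libraries except for the spread. BIRC3 stood at -2.19 (SE 0.23) under RPL27 siRNA, at -2.02 in HCT116 and -2.36 in HT29, COL6A3 at 3.45 (SE 0.34), and the complement gene C2 at 2.23 (SE 0.37) under RPL9 and -2.98 (SE 0.37) under RPL17 siRNA. With all 8 libraries limma called 0 genes in each of these comparisons, with 690, 517 and 601 genes at an unadjusted p under 0.05 for RPL9, RPL17 and RPL27. Without the HT29 NC library 102, 62 and 178 genes were called, and without the HCT116 NC library 94, 60 and 177. On the 6 RPL siRNA libraries alone 47 genes were higher and 54 lower for RPL9, 19 and 41 for RPL17, and 68 and 111 for RPL27. The targets were then called: RPL9 at -1.75 (adjusted p = 4.6e-05), RPL17 at -1.66 (0.0010) and RPL27 at -1.69 (0.00077). BIRC3 (adjusted p = 0.0075), COL6A3 (0.023) and C2 (0.035 and 0.030) were called as well.

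Cell cycle genes parted the siRNAs in size. Under RPL17 siRNA all 30 G2/M genes and 31 of 32 G1/S genes stood above the other two RPL siRNAs, with medians of 0.46 and 0.40 (camera adjusted p = 1.6e-19 and 1.0e-15), and under RPL27 siRNA 29 and 31 of them stood below, with medians of -0.44 and -0.30 (4.1e-14 and 5.4e-12). With an estimated correlation the adjusted p values were 0.49 and 0.16 for RPL17 and 0.49 and 0.24 for RPL27. The order held in both lines, with G2/M medians of 0.58 and 0.34 under RPL17 and -0.46 and -0.36 under RPL27 siRNA in HCT116 and HT29. Over all genes and adjusted over the list alone 0 members were called by limma. RPL9 siRNA stood above the others in NF-kB targets (0.43; camera adjusted p = 0.0014), immediate early genes (0.27; 0.0014), ribosome biogenesis factors (0.11; 0.0032), ATF4 response genes (0.10; 0.018) and intestinal differentiation genes (0.37; 0.025), each with adjusted p = 0.39 with an estimated correlation. RPL27 siRNA stood below the others in NF-kB targets (-0.24; 0.0063, and 0.49 with an estimated correlation) and ribosome biogenesis factors (-0.12; 0.011, and 0.63). Of these lists limma called 0 members over all genes, and adjusted over the list alone 2 ATF4 genes and 1 immediate early gene were higher under RPL9 siRNA and 1 NF-kB target lower under RPL27 siRNA.

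The difference of the RPL siRNA effect between HCT116 and HT29 asks whether the lines respond differently. MDM2 went up by 2.06 in HCT116 and 4.13 in HT29, a difference of -2.07 (SE 0.33; adjusted p = 0.0042), which was -0.41 (adjusted p = 0.54) after length correction. CDKN1A differed by 0.23 (SE 0.23; adjusted p = 0.51). RPL11 differed by 1.10 (SE 0.12; adjusted p = 0.0012), and by 0.48 (adjusted p = 0.064) after length correction. The other genes named by size were DENND2A (5.11), ANXA8L2 (5.10), RND2 (4.41), SPINK13 (4.08), GPD1 (3.82) and TRIM10 (3.80) toward HCT116 and LMBRD2 (-6.23), MAST4 (-5.83), JAKMIP2 (-5.58), AOAH (-5.45), RAB27B (-5.08) and POTEF (-5.05) toward HT29. After length correction SPINK13 (adjusted p = 0.12) and AOAH (0.056) no longer passed, and both also missed the threshold, as did ANXA8L2, when some single RPL siRNA libraries were left out (highest adjusted p = 0.061, 0.054 and 0.080).

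Limma called 3266 genes in this comparison, 873 with a positive difference (HCT116 minus HT29) and 2393 with a negative one, whichever line moved more. Both counts rest on 1 NC library per line, so the fit cannot tell a difference between the lines from a deviation of the HT29 NC library. After length correction 466 and 599 genes were called, of which 758 had been called before, 753 of them in the same direction. Quantile normalization gave 1352 and 1717 genes and median-centring 2131 and 1404, which turns the balance of directions. Among lists, large subunit ribosomal proteins (median 1.02; 39 members called higher over all genes and 43 adjusted over the list alone), small subunit ribosomal proteins (1.14; 31 and 32) and translation factors with 5' TOP messages (0.48; 10 and 13) had a positive difference by camera (adjusted p = 4.6e-30, 5.6e-27 and 7.2e-07). With an estimated correlation the adjusted p values were 0.17 for all 3. Of the 6 ribosomal protein paralogs 4 were called higher and 1 lower (median 1.29; camera adjusted p = 0.032; adjusted p = 0.35 with an estimated correlation). After length correction the medians were 0.46, 0.51, 0.48 and 0.52, and the paralogs passed no longer (0.21). Under quantile normalization the translation factors stood at 0.09 and passed no longer (0.91), nor did the paralogs (0.12), which also missed under median-centring (0.078). Ribosome biogenesis factors (0.30; 0.12) passed after length correction (0.35; 0.0011), after length and GC correction (0.42; 0.00021), under median-centring (0.74; 0.013), and without the HCT116 RPL27 siRNA or the HT29 RPL9 siRNA library (0.035 and 0.040). In these 5 settings the adjusted p was 0.77 to 0.94 with an estimated correlation. ID genes and BMP targets passed without a filter (0.78; 0.049, and 0.58 with an estimated correlation).

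Within each line, an absolute log2 difference of at least 1 from the NC library was reached by 2115, 1635 and 1794 genes under RPL9, RPL17 and RPL27 siRNA in HCT116 and by 5005, 4681 and 4733 genes in HT29. These counts compare single libraries and have no replicate check. G2/M genes lay below all of 10000 random lists matched on level in the 6 comparisons. Their medians were -1.14, -0.75 and -1.41 in HCT116 and -0.68, -0.55 and -0.97 in HT29. The random lists are drawn gene by gene and do not keep the correlation of list members, so these ranks are descriptions. In HT29 both ribosomal protein lists also lay below all of them. With lists matched on length too, G2/M genes stayed below all, and the ribosomal protein lists in HT29 stood at percentiles of 0.135 to 10.96. Fold changes of the same siRNA in the 2 lines had a mean Pearson correlation across genes of 0.20, and those of different siRNAs 0.16. Genes are not independent replicates, so these correlations carry no p value. For the siRNA-specific part, which leaves out the NC libraries, the mean correlation between lines was 0.22 (Spearman 0.32).

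Within a line the fold changes of 2 siRNAs share the NC library and correlate for that reason alone. The Pearson correlation across genes was 0.66 to 0.70 in HCT116 and 0.84 to 0.88 in HT29, where simulated unchanged groups with a shared control gave 0.49 to 0.51 if NC varies like the RPL siRNA libraries. The covariance was 0.33 to 0.38 in HCT116 and 1.05 to 1.08 in HT29, against 0.088 to 0.092 in the simulation. A wider spread of the NC libraries would raise the simulated values, so part of the excess may come from the shared NC library, and these correlations alone do not show a shared effect. With 1 NC library per line the control could not be split between the siRNAs.

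HCT116 and HT29 were compared over all siRNAs. Genes of intestinal epithelium were far lower in HCT116: AGR2 by -9.67 (SE 0.68), LGALS4 by -9.44 (SE 0.67), TSPAN8 by -8.94 (SE 0.36), LYZ by -8.36 (SE 0.29) and VIL1 by -7.89 (SE 0.35), with adjusted p values of 0.0018, 0.0018, 0.00043, 0.00033 and 0.00045. POF1B, TXNIP, TM4SF4, SCEL and UGT1A6 followed, at -8.47 to -7.77. Genes higher in HCT116 were led by SCN9A (3.86), ZBED2 (3.54), DSC3 (3.36), FAM49A (2.98), C10orf11 (2.95), EIF4E3 (2.93), LCP1 (2.66), TMEM154 (2.58), ILDR2 (2.53) and NKAIN1 (2.47). Of these 10 genes, all but DSC3 (62.8) and EIF4E3 (22.2) had mean levels of only 2.90 to 7.86 RPKM. The 10 genes named as lower in HCT116 had means of 154 to 1308 RPKM. Limma called 96 genes higher in HCT116 and 412 higher in HT29. Without any 1 of the RPL siRNA libraries 177 to 193 were called, without the HCT116 or the HT29 NC library 3232 and 3265, and without both 1584 higher and 1674 lower, among them all 508 in the same direction. All 10 genes named as lower in HCT116 kept their call in every alternative. Of the 10 named as higher only SCN9A did, and the others had an adjusted p of up to 0.18 when 1 RPL siRNA library was left out.

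Intestinal differentiation genes as a list stood at -1.34 in HCT116 against HT29, with 11 of 19 called lower over all genes and 12 adjusted over the list alone (camera adjusted p = 1.2e-09; adjusted p = 0.24 with an estimated correlation). In this comparison, leaving out either library of an siRNA drops that siRNA from the line estimate. Settings without the HCT116 library, the HT29 library or both libraries of an siRNA thus share the same estimate and are not separate checks. Ribosome biogenesis factors stood at 0.22 (camera adjusted p = 0.0084; adjusted p = 0.67 with an estimated correlation), with 0 members called by limma over all genes and 0 adjusted over the list alone. They missed the threshold at 0.084 and 0.084 without the HCT116 or HT29 RPL17 siRNA library, and at 0.061 under median-centring. ID genes and BMP targets (-0.43; 0.033) and interferon-stimulated genes (-0.19; 0.033) had adjusted p values of 0.67 and 0.50 with an estimated correlation. Without the HCT116 NC library they missed the threshold (0.23 and 0.12), as they did without the HT29 NC library (0.24 and 0.12), without both (0.26 and 0.12), under quantile normalization (0.084 for both) and median-centring (0.070 and 0.059), after length correction (0.33 and 0.12, with ID genes and BMP targets at -0.18) and after length and GC correction (0.36 and 0.11). With a mean of at least 5 interferon-stimulated genes missed it (0.061), and interferon-stimulated genes also did without the HCT116 or HT29 RPL27 siRNA library (0.053 and 0.052). Large and small subunit ribosomal proteins stood at -0.24 (8.9e-05) and -0.27 (0.0015; both 0.80 with an estimated correlation), and at 0.04 and 0.02 without the HCT116 NC library, the HT29 NC library or both. Ribosomal protein paralogs (0.21; 0.66) passed at 0.39 without the HCT116 NC library (0.034), the HT29 NC library (0.035) or both (0.034), and histones (-0.41; 0.12) at -0.49 without the HCT116 or HT29 RPL9 siRNA library (0.048 and 0.047) and at -0.14 without a filter (0.026). In these settings the adjusted p with an estimated correlation was 0.62 for the paralogs and 0.68 to 0.80 for histones.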

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

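Except for the splits of the libraries, which were planned, the tests of explanations here were chosen after the result was seen. Of 16 sets of 4 libraries examined for a library far from the others of its line, 7 had one. Each was an NC library. A chance rate of about 1 in 20 holds only for independent sets of libraries treated alike. Here the measures share the same libraries, and NC is the only library of its line without an RPL siRNA. The deviations were also taken from a mean that left out only HT29 NC. The count therefore cannot tell an effect of the siRNAs from a fault of the NC libraries. In HT29 NC the sum of RPKM times kb was 16.9 M (21.4 to 21.6 in the other libraries of the line), the 10 highest genes held 7.03% of the RPKM sum (5.74% to 5.95%), the rank correlation of the deviation with transcript length was -0.64 (-0.01 to 0.09), the SD of the deviation was 1.01 (0.37 to 0.43), and the rank correlation with the line mean was 0.85 (0.97). In HCT116 NC the sum was 21.2 M (21.5 to 21.6) and the SD 0.47 (0.33 to 0.34).

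The length trend of the HT29 NC library was weighed first. A length-dependent response to RPL siRNAs shared by both lines is argued against by HCT116 NC, whose deviation had a rank correlation of 0.037 with length. A library of HCT116 under the HT29 NC label is argued against by 85 genes that were higher in HT29. Their median log2(RPKM + 1) was 6.55 in HT29 NC, 6.97 to 7.18 in the other HT29 libraries and 0.19 to 1.14 in HCT116. These genes were chosen only to part HCT116 from HT29, so they cannot speak to any other cell line. A length bias of this library may explain the trend, which had a rank correlation of -0.70 over 1745 genes that did not change in HCT116. This and a response of HT29 alone cannot be told apart with 1 NC library.

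The interaction test called a difference of the RPL siRNA effect between the lines in 3266 genes and 4 lists. It holds 1 NC library per line and so no spread between NC libraries, and after length correction 758 of these genes were called again. Positive differences (HCT116 minus HT29) were those of DENND2A (5.11), ANXA8L2 (5.10), RND2 (4.41), SPINK13 (4.08), GPD1 (3.82), TRIM10 (3.80) and RPL11 (1.10). Negative ones were those of LMBRD2 (-6.23), MAST4 (-5.83), JAKMIP2 (-5.58), AOAH (-5.45), RAB27B (-5.08), POTEF (-5.05) and MDM2 (-2.07). The list medians were 1.02 for large and 1.14 for small subunit ribosomal proteins, 1.29 for ribosomal protein paralogs and 0.48 for translation factors with 5' TOP messages. Each rests on the HT29 NC library with the trend above. After length correction SPINK13 (3.22, adjusted p = 0.12), AOAH (-5.36, 0.056), RPL11 (0.48, 0.064) and MDM2 (-0.41, 0.54) passed no longer, nor did the paralogs (0.52, 0.21), which also missed under quantile normalization (0.12) and median-centring (0.078), as the translation factors did under quantile normalization (0.91). With an estimated correlation the adjusted p was 0.17 for 3 lists and 0.35 for the paralogs. DENND2A and the others with a matched length kept their call.

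RPL27 mRNA was lower under RPL17 siRNA in both lines. A general fall of ribosomal protein mRNAs is argued against by the median of the 76 other ribosomal protein genes, RPL17 against RPL9 siRNA, which was -0.12 in HT29 and 0.01 in HCT116, with RPL27 at -1.15 and -0.97 below all of them. Mixing of the RPL17 and RPL27 siRNA libraries is argued against by RPL17, which stood at 50.7% and 41.3% of the lowest level that mixing allows in HCT116 and HT29. An effect of the RPL17 siRNA outside its target may lower RPL27 to the level seen, 50.9% of the RPL9 siRNA library in HCT116 and 45.15% in HT29 (61.7% and 29.3% of NC), and stays open without a second siRNA.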

How the results depend on the processing

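The length corrections, the fits without both NC libraries and those of 1 line alone were chosen after the result was seen. Under planned settings with all libraries, 1715 values of named genes kept direction and side of the threshold, 111 lost a call, 24 gained one and 16 moved, and of the list medians 455 kept both, 13 lost a call, 6 gained one and 27 moved. With a library left out, 1475 gene values kept both, 193 lost and 163 gained a call, 44 moved and 5 reversed; of list medians 476 kept both, 16 lost, 13 gained, 16 moved and 7 reversed. Under the later settings 426 gene values and 135 list medians kept both, 9 and 8 lost and 93 and 7 gained a call, 16 and 16 moved and 2 list medians reversed. No gene symbol was repeated, so the choice among repeated symbols was not run. The interaction gave no value without the line term or without an NC library.

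The mean contrast called 24 genes, 10 with a pseudocount of 0.1, 9 with 5, 10 without a filter, 83 under quantile normalization, 7 under median-centring, 0 without the trend and with robust variances (limma), 6 without the line term, 693 for any RPL siRNA against NC, 873 after length and 1196 after length and GC correction, 0 in HCT116 alone (2532 at an unadjusted p under 0.05) and 4852 in HT29 alone. The RPL9 contrast called 4 with a mean of at least 5, 10 under quantile normalization, 2 under median-centring, 0 without the trend and with robust variances, 0 without the line term, 538 after length and 853 after length and GC correction. The RPL17 contrast called 0 without a filter, 10 under quantile normalization, 0 under median-centring, without the trend and with robust variances, or without the line term, 52 after length and 103 after length and GC correction. The RPL27 contrast called 1 under quantile normalization, 272 after length and 471 after length and GC correction. The siRNA-specific contrasts called 2, 2 and 1 under quantile normalization, 1 for RPL9 and 1 for RPL17 after length correction, and 101, 60 and 179 without both NC libraries. The interaction called 1065 after length and 948 after length and GC correction. The comparison of the lines called 1032, 1163 and, without both NC libraries, 3258. The cause was not tested. Single-line fits hold fewer libraries, but that alone does not explain why 1 line gave fewer genes than all 8 libraries and the other more.

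With 1 library left out, counts ranged from 0 to 6597 (RPL9), 6314 (RPL17), 6374 (RPL27) and 6948 (mean), from 0 to 102, 62 and 178 (siRNA-specific), from 2509 to 3157 (interaction) and from 177 to 3265 (lines). Except in the interaction, which had no such fit, the highest are without an NC library, where the spread comes from RPL siRNA libraries and the lone NC library is assumed to vary like them. The lowest are without an RPL siRNA library, and the cause was not tested.

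In single libraries a size rule of log2 of 1.5 gave 4812, 3953 and 4266 genes in HCT116 and 8212, 8062 and 8071 in HT29. The correlation between lines was 0.20, and 0.25 after length correction, 0.23 with a mean of at least 5 and 0.17 with a pseudocount of 0.1.

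With 1 library left out, values reversed without the HT29 NC library, which gave the highest of each range: RPL27 under RPL9 siRNA (-0.66 to 0.32), RPL11 under RPL9 (-0.73 to 0.36), RPL17 (-0.65 to 0.45) and RPL27 siRNA (-0.75 to 0.35) and in their mean (-0.71 to 0.39), and in the mean contrast large (-0.91 to 0.20) and small subunit ribosomal proteins (-0.995 to 0.23) and translation factors with 5' TOP messages (-0.37 to 0.14). In the mean contrast the ends of these ranges are the values of HT29 and of HCT116 alone, since only the NC library of that line is kept. Between the lines, large (-0.33 to 0.035) and small subunit ribosomal proteins (-0.37 to 0.018) reversed without the HCT116 NC or the HT29 NC library. They stood at the same 0.035 and 0.018 without both. In these settings the line estimate comes from the RPL siRNA libraries alone, so they share an estimate and are not separate checks. The reversals thus follow from which NC library is kept. Why the NC libraries differ in these genes was not tested here. All 21 genes that the naming rule picked among those called in the mean contrast kept their sign in each alternative, and 0 kept the call in all. The rule took only genes with the same direction in every RPL siRNA library against NC. Leaving out a library or taking 1 line alone therefore could not reverse their sign, and these fits are no check of it. Of 14 named genes called in the interaction 9 kept the call in all alternatives, and of 20 between the lines 11. Depth limits genes of few reads, and read counts were not analysed here.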

Other observations

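The tests and values here other than the splits of the libraries were chosen after the result was seen. For HCT116 against HT29, 35 splits of the 8 libraries into 4 and 4 exist, and 32 could be fitted. Only 1, the real one, gave as many genes (508), and the highest other gave 0, a share of 1 in 32. The other splits mix the lines in each group, so that line differences widen their spread and lower their counts. The splits therefore cannot exclude chance for this count.

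Line differences were lopsided. Among RPL siRNA libraries 85 genes were higher in HT29 by more than 4 (log2) in all libraries and 0 were higher in HCT116, where the largest gap was 3.79 against 8.11. By more than 2 the numbers were 235 and 8. Of 6614 genes at 100 RPKM or more in HCT116, 0 lay below 10% and 14 below 50% of the HCT116 level in all 3 HT29 libraries, while of 6626 such HT29 genes 51 and 155 did in HCT116. DSC3 was lowest, at 15.8%. Between the NC libraries 8 of 7033 HCT116 genes lay below 10% in HT29, 105 below 25% and 685 below 50%, and of 6894 HT29 genes 52, 115 and 575 in HCT116. Taken 1 siRNA at a time, 6, 2 and 3 HCT116 genes lay below 25% in HT29 under RPL9, RPL17 and RPL27 siRNA, and 112, 102 and 85 HT29 genes in HCT116. RNA of HCT116 cells in the HT29 RPL siRNA libraries, at a share of 10% or more, would leave 0 genes below 10% there, as seen, but the 8 between the NC libraries are too few to decide it. The counts below 25% go the way such RNA would move them, but they are set against 1 HT29 NC library, after removal of its length trend, so a part of HCT116 RNA there stays open. As the whole source of the changes in HT29 of the 24 genes called in the mean contrast it is argued against: they would need a share of 97.9%, and 291 of the 6614 genes lay below 0.75 of that share in all 3 libraries. These 24 genes were picked for like changes in both lines, which raises the share they need.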
